A study of Rattus norvegicus with 24 samples.

How the data were processed

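Total RNA from gastrocnemius muscle of 24 female rats, aged 8 months and of generation 18 per the labels, was extracted with Trizol, converted to biotin-labelled cRNA with an Illumina amplification kit and hybridised to 1-colour Illumina arrays, per the labels' protocols. The labels put 12 rats in the HCR line and 12 in the LCR line, and number each rat, so that p-values measure the spread between separate animals. How many dams or litters they came from, and on which slide each array lay, is not given in the sources used here.

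The authors deposited a non-normalized table with 22517 probes and, for each rat, an intensity on a linear scale and a detection p-value. Per the file headers each intensity column carries a rat number, which matches 1 sample's label, and 0 per-sample columns were left without a sample. The intensities are never negative and are neither normalized between arrays nor background subtracted, from their values. The deposited detection p-value steps in units that fit a rank among about 825 negative control probes, which are not used here as such. The deposited series table holds a second intensity per probe and rat. Set against the scanner values, each of the 24 columns ranked probes as its own raw column (rank correlation 1.0, against at most 0.951 with any other), and each has a median of 92.4, so that it is on a linear scale, uncentred, and has the properties of quantile normalization without background correction. The submitters' processing notes name the tool affy, with no version, and the scanner software is not given in the sources used here.

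Probes were named from the platform annotation supplied with the series: 13787 probes have 1 gene symbol, 0 have several and 8730 are not listed and stay unnamed. Symbols were looked up in the RefSeq gene table of assembly GRCr8, 13747 through the Entrez identifier and 5 through the accession, which changed 0 symbols, and 35 kept the annotation's symbol. That table was used only for names and for which genes neighbour each other. No genome build is named for the array, and no coordinates are given.

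Intensities were background corrected with the normal-exponential model of limma's neqc, which infers the controls from the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale. A probe was tested if its detection p was under 0.05 on at least 6 of the 24 arrays, which left 10384 probes and 7317 genes. The lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene with several tested probes is represented by the probe with the highest mean over all arrays. The number of arrays limits the precision, and a probe near background is compressed towards the floor. Called genes undetected on all arrays of a line numbered 0.

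Fixed before the data were examined were 30 gene lists with 732 entries, 606 of which have a named probe: fatty acid oxidation and lipid handling, the mitochondrial and peroxisomal lists, amino acid, glucose and insulin lists, fibre types, markers of other cell types in whole muscle, and stress, clock, immediate early, atrophy and ribosomal lists. The 29 lists with at least 5 tested genes were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 29. With an estimated correlation 0 lists passed the threshold. The directional fry test, which asks whether the genes of a list move on balance one way, called 6 lists, 4 of them among the 7 of camera (not beta-oxidation, the tricarboxylic acid cycle or complexes III and IV), and its mixed form 9. A list level is the mean, over its genes, of log2 values centred on the mean of the 24 arrays. The probe test and the list test were run on simulated log2 values. With 200 shifted probes, 10 of 10184 unchanged probes were called (5.7% of calls) and 0 changed probes had the wrong direction. In a separate simulation the 1 shifted list was the 1 list called. Values were drawn independently for each probe, whereas the estimated correlation of the beta-oxidation list was 0.591. The simulation therefore cannot show how the list test behaves where genes vary together. Background correction, normalization and the filter were not part of it.

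The rule for named genes, also fixed in advance, takes the 10 genes with the largest difference in each direction among those past the threshold, with placeholder symbols counted and not named, up to 4 members past the threshold with the smallest adjusted p from each list, and 18 genes named whatever their result. Of these 18, Ppara, Myh1 and Pecam1 gave no value.

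Alternatives fixed in advance were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' processed values, 3 other filters on dim probes, a trended and robust variance, array weights, rats 1 to 12 and rats 13 to 24 (6 per line in each) as batches, entered as a block and analysed alone, the replicate number as a block, each array left out, a threshold of 0.01, and for the lists an estimated correlation, fry and all probes of a gene. These batches stand in for the slide, which the files do not give, and 279 probes differed between them. Chosen after the data were seen were leaving out LCR replicate 5 and HCR replicate 11, and the slow fibre level or the log2 ratio of Myh2 to Myh4 as a covariate, each with and without those 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.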

Results

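Gene expression was measured in the gastrocnemius, the large calf muscle, of 24 female rats from a pair of lines derived by artificial breeding from one genetically mixed stock. The HCR rats are runners of high inborn aerobic capacity and the LCR rats of low capacity. Each line gave 12 rats, each rat was hybridised to its own Illumina expression array, and the comparison asks how the muscle of the lines differs in RNA levels. With a single line of each kind, a difference cannot be assigned to running capacity rather than to anything else in which the lines differ. The median raw signal of an array lay between 87.4 and 98.2, and 9185 to 10089 of the 22517 probes were detected per array (40.8% to 44.8%). After normalization, 10384 probes for 7317 named genes were tested. Differences are given on the log2 scale as HCR minus LCR with their standard error, from 12 rats per line, with Benjamini-Hochberg adjusted p from limma; they are relative to the other transcripts on the array.

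The largest difference in favour of HCR among named genes past the threshold was that of Ptgr2, which encodes a prostaglandin reductase, at 8.48 ± 0.42 (SD, n = 12) against 6.73 ± 0.89 (SD, n = 12) in LCR, a 3.35-fold difference (1.75 ± 0.27 log2, adjusted p = 4.90e-04). Cd2bp2, a splicing factor of the U5 snRNP, was 1.67 ± 0.34 higher and Retsat, the retinol saturase, 1.38 ± 0.27 higher (adjusted p = 0.0075 and 0.0054). Zfp317, a zinc finger gene, was 1.00 ± 0.14 higher (adjusted p = 1.46e-04), with a signal of 5.76 to 7.30 on the HCR arrays and 5.23 to 5.86 on the LCR arrays. Plb1, a phospholipase gene, was 0.89 ± 0.16 higher and Cpt1a, whose product brings long-chain fatty acids into mitochondria, 0.79 ± 0.17 higher (adjusted p = 0.0026 and 0.0085). Oas1k, of the oligoadenylate synthetase family, and the class I histocompatibility gene RT1-CE15 were 0.88 ± 0.21 and 0.85 ± 0.20 higher (adjusted p = 0.0171 and 0.0202). The beta-globin gene Hbb-b1 and the glycerol channel gene Aqp7 completed the 10 largest of those past the threshold, at 1.01 ± 0.27 and 0.92 ± 0.24 (adjusted p = 0.0375 and 0.0301). Leaving out 1 array ended the call of Hbb-b1 in 12 of 24 fits and that of Aqp7 in 6, with adjusted p of up to 0.0628 without HCR replicate 4 and 0.0554 without LCR replicate 10. The size of dim genes depends on the background step. Without background correction Zfp317, Aqp7, Oas1k, RT1-CE15 and Cpt1a differed by 0.53, 0.54, 0.49, 0.52 and 0.45, and all 5 passed.

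Higher in LCR muscle were the class I histocompatibility genes RT1-A2 and RT1-A1, with differences of -2.36 ± 0.42 and -2.34 ± 0.61 (adjusted p = 0.0022 and 0.0330). The RT1-A2 probe was detected on 12 of 12 LCR arrays and on 3 of 12 HCR arrays, so that the size of its difference rests on signal near background in HCR. Without background correction it was -1.45 (adjusted p = 0.0039). RT1-A1 ranged from 5.48 to 10.64 among HCR rats and from 7.91 to 11.22 among LCR rats, and its call ended in 8 of the 24 fits that left out 1 array (adjusted p of up to 0.0592, without HCR replicate 1). Mrps10, a protein of the small mitochondrial ribosome subunit, averaged 5.82 ± 0.56 in HCR and 7.77 ± 0.51 in LCR (SD, n = 12 each), a difference of -1.96 ± 0.20 (adjusted p = 1.84e-06), and all 12 LCR arrays lay above the HCR median. The aldo-keto reductase gene Akr1b10 differed by -1.16 ± 0.14 (adjusted p = 1.86e-05), with the LCR arrays at 8.03 to 8.54 and the HCR arrays at 6.34 to 7.73. Rfc2, a subunit of the replication clamp loader, differed by -1.40 ± 0.20 and the interferon-induced gene Ifit1 by -1.37 ± 0.24 (adjusted p = 2.53e-04 and 0.0019). Plekhf2 differed by -1.48 ± 0.32 and Eef2k, the kinase that acts on the translation elongation factor eEF2, by -1.32 ± 0.31 (adjusted p = 0.0094 and 0.0161). The growth factor gene Igf2 and the immediate early gene Egr1 differed by -1.22 ± 0.26 and -1.20 ± 0.30 (adjusted p = 0.0094 and 0.0243). Between rats 1 to 12 and 13 to 24 the difference went from -1.70 to -0.75 for Igf2 and from -0.67 to -1.74 for Egr1. Their spread was wider among LCR rats, with an SD of 0.94 against 0.24 for Igf2 and of 1.05 against 0.37 for Egr1. Without background correction Mrps10, Plekhf2, Rfc2 and Ifit1 differed by -1.21, -0.87, -0.76 and -0.76, and all 4 passed. The probes of Plekhf2, Rfc2 and Ifit1 were detected on 5, 7 and 5 of the 12 HCR arrays.

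**Figure D1:**
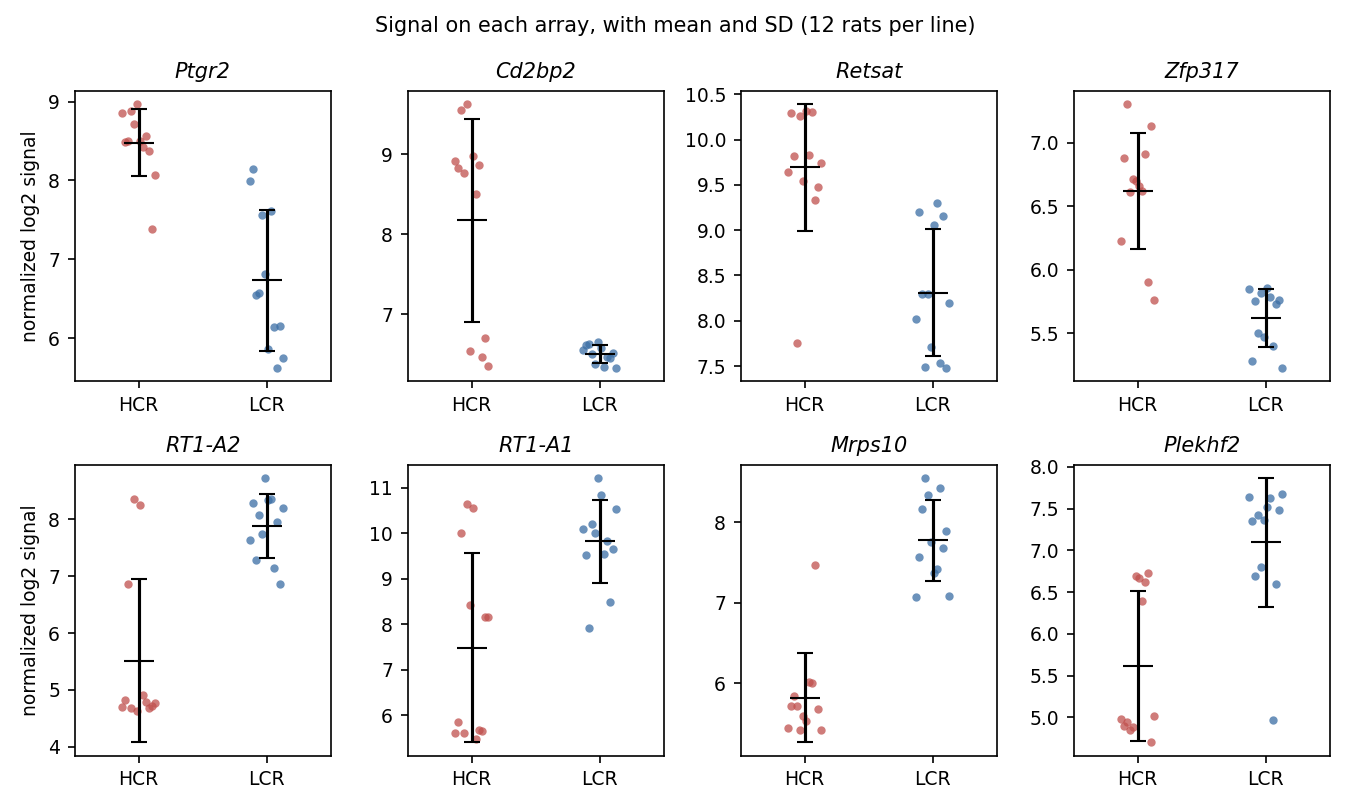
Normalized log2 signal (vertical axis) of 4 genes higher in HCR (top) and 4 higher in LCR (bottom). Each point is the array of 1 rat, and black marks and bars give the mean and SD of the 12 rats of a line. Cd2bp2 ranges from 6.36 to 9.63 in HCR and from 6.33 to 6.65 in LCR, while Mrps10 lies at 5.42 to 7.47 in HCR and 7.07 to 8.55 in LCR.

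In all, 284 genes passed an adjusted p of 0.05, 143 higher in HCR and 141 higher in LCR, from 401 of the 10384 probes. The median size of their differences was 0.42, and 15 genes differed by over 1 log2, 4 of them higher in HCR and 11 higher in LCR. Without background correction 9 genes did. For 4 of these 15, Cd2bp2, RT1-A1, RT1-A2 and Plekhf2, the arrays of a line fell into 2 sets separated by a gap of over 1 log2. All HCR arrays lay above all LCR arrays for 1 of the 284 genes, and the reverse held for 2. Of the 401 probes, 114 have no gene name here, among them the probe with the largest difference of the 401, ILMN_1349205, at -4.02 ± 0.41. For 5 of the 284 genes a second probe was tested: that of Qprt also passed, those of Elf2, Epb41l1 and Farp1 did not, and that of Il17rb had the opposite sign. Scaling arrays to a common median in place of quantile normalization gave 243 genes higher in HCR and 102 higher in LCR, which is 70.4% higher in HCR in place of 50.4%. Single arrays moved the counts: 250 probes passed without HCR replicate 1 and 264 without LCR replicate 9, 94 genes were higher in HCR without HCR replicate 1, and 91, 91 and 93 were higher in LCR without HCR replicate 1, LCR replicate 10 and LCR replicate 12. No slide is given for the arrays, and rats 1 to 12 and 13 to 24 were taken as batches in its place. With these batches as a block, 323 genes passed, 281 of them among the 284. Within rats 1 to 12 alone 27 genes passed and within rats 13 to 24 alone 56, with 6 rats per line in each, and 24 and 45 of these were among the 284.

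Genes of mitochondrial fatty acid beta-oxidation were higher in HCR muscle as a group. All 22 tested members had a positive difference, with a median of 0.22 (camera adjusted p = 4.16e-07; adjusted p = 0.422 with an estimated correlation and 0.0830 by the directional fry test). Cpt1a, given above, and Hadhb, a subunit of the mitochondrial trifunctional protein, passed over all genes, Hadhb at 0.25 ± 0.06 (adjusted p = 0.0132), and 8 members passed when adjusted over the list alone. The muscle isoform Cpt1b differed by 0.21 ± 0.11, Hadha by 0.17 ± 0.13 and the uncoupling protein gene Ucp3 by 0.37 ± 0.33, none of which passed (adjusted p = 0.329, 0.571 and 0.627). Hadha differed by 0.099 without LCR replicate 5 and Ucp3 by 0.195 without LCR replicate 12. The mean difference of the list was 0.22 in rats 1 to 12 and 0.29 in rats 13 to 24 (camera adjusted p = 0.0028 and 7.60e-09), and the list passed with the batch as a block (4.77e-07). Among rats 1 to 12 the list level was -0.86 on LCR replicate 5, 0.03 to 0.12 on the other LCR arrays and -0.20 to 0.40 on the HCR arrays. The mean difference in that batch therefore leaned on LCR replicate 5, and no permutation by rat was run for this list. The list level was lowest on LCR replicate 5, at -0.86 against a mean of -0.13 ± 0.28 in LCR and 0.13 ± 0.20 in HCR (SD, n = 12 each). The difference went along with the signal of Myh2, the type IIa myosin heavy chain, relative to Myh4, the type IIb chain: log2 Myh2 minus log2 Myh4 was 0.02 ± 0.84 in HCR and -1.08 ± 1.40 in LCR (SD, n = 12 each; two-sided permutation p = 0.0259 over 100000 permutations). The ratio was lowest on LCR replicate 5, at -4.32. Without LCR replicate 5 and HCR replicate 11 the ratio differed by 0.83 between the lines in place of 1.09, a value that was not tested. With that ratio as a covariate, chosen after the data were seen, the median difference of the list was 0.03 (camera adjusted p = 0.333), and without LCR replicate 5 and HCR replicate 11 it was 0.08 (0.0149). In that last fit adipocyte markers also passed as higher in HCR (0.0149). The covariate ended the call of Hadhb (adjusted p = 0.0565, and 0.0718 without the 2 arrays) and, without the 2 arrays, that of Cpt1a (0.0707). With it and all arrays Cpt1b differed by 0.02 and Hadha by -0.02.

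Genes of fatty acid uptake and lipid droplet handling were also higher in HCR, 15 of 18 with a positive difference and a median of 0.22 (camera adjusted p = 0.0027; adjusted p = 0.296 with an estimated correlation). Gpihbp1, which holds lipoprotein lipase on the capillary surface, rose by 0.58 ± 0.13 in HCR against LCR, and Pnpla2, the adipose triglyceride lipase, by 0.48 ± 0.13 (adjusted p = 0.0151 and 0.0330). Without background correction Gpihbp1 differed by 0.29. The Pnpla2 call ended in 8 of the 24 fits that left out 1 array, with 0.0601 without HCR replicate 1, and 3 members of the list passed when adjusted over the list alone. The fatty acid translocase gene Cd36 and the fatty acid binding protein gene Fabp3 differed by 0.26 ± 0.16 and 0.31 ± 0.25 and did not pass (adjusted p = 0.450 and 0.581). They differed by 0.15 and 0.13 without LCR replicate 5 and by -0.03 and -0.13 with the Myh2 to Myh4 ratio as a covariate. The list mean was 0.23 in rats 1 to 12 and 0.24 in rats 13 to 24 (camera adjusted p = 0.0206 and 0.0078; 0.0037 with the batch as a block). With the Myh2 to Myh4 ratio as a covariate the adjusted p was 0.316, and with it and without LCR replicate 5 and HCR replicate 11 it was 0.0402, a fit in which adipocyte markers passed as well (0.0149). That covariate ended the call of Pnpla2 (0.32, adjusted p = 0.179, and 0.158 without the 2 arrays) and, without the 2 arrays, that of Gpihbp1 (0.0702). Among probes detected on all 24 arrays it was 0.0511.

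Members of the tricarboxylic acid cycle list and of the list of respiratory complexes III and IV with cytochrome c showed small positive differences, in 17 of 19 and 14 of 15 genes, with medians of 0.09 and 0.06. Both lists passed (camera adjusted p = 0.0141 and 0.010; adjusted p = 0.663 and 0.611 with an estimated correlation and 0.206 and 0.107 by the directional fry test), while none of their members passed over all genes, and 0 and 3 passed when adjusted over the list alone. Citrate synthase, Cs, a common marker of mitochondrial content, differed by -0.03 ± 0.13 (95% interval -0.30 to 0.24, adjusted p = 0.943). Both calls ended without LCR replicate 5 (adjusted p = 0.157 and 0.0913), and that of the tricarboxylic acid cycle also without HCR replicate 6 (0.0514) or HCR replicate 12 (0.0549). The cycle list had adjusted p of 0.113 and 0.0525 within rats 1 to 12 and 13 to 24 (0.0151 with the batch as a block), and the complexes 0.248 and 0.0047 (0.0089). With the Myh2 to Myh4 ratio as a covariate the adjusted p were 0.923 and 0.707, and the median of the cycle list was -0.016. With that covariate and without LCR replicate 5 and HCR replicate 11 the adjusted p were 0.497 and 0.478.

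Genes of branched-chain amino acid breakdown had a positive difference in 10 of 12 cases, with a median of 0.16 (camera adjusted p = 0.010; adjusted p = 0.296 with an estimated correlation; 4 higher in HCR and 1 higher in LCR when adjusted over the list alone). Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, and the acyl-CoA dehydrogenase gene Acadsb were 0.37 ± 0.08 and 0.46 ± 0.11 higher in HCR (adjusted p = 0.0094 and 0.0226). Without background correction Acadsb was 0.22 higher. Mccc1, of leucine breakdown, was 0.20 ± 0.06 higher (adjusted p = 0.0423), a call that ended in 14 of the 24 fits that left out 1 array, with 0.0734 without HCR replicate 1. Pccb, a propionyl-CoA carboxylase subunit, was higher in LCR (-0.38 ± 0.08, adjusted p = 0.0075; -0.22 without background correction). The list had adjusted p of 0.189 and 0.0040 within rats 1 to 12 and 13 to 24, 0.0094 with the batch as a block, and 0.146 with the Myh2 to Myh4 ratio as a covariate (0.0149 with that covariate and without LCR replicate 5 and HCR replicate 11, where adipocyte markers passed too). The call of Mccc1 ended with that covariate (0.137).

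Genes of the interferon response and antigen presentation moved in both directions. Of 28 tested, 22 had a positive difference, with a median of 0.15 and, RT1-A1 and RT1-A2 included, a mean of -0.004 (camera adjusted p = 0.0023 for higher in HCR; adjusted p = 0.296 with an estimated correlation). Tapasin, encoded by Tapbp, B2m, the light chain of class I molecules, and the peptide transporter gene Tap2 were higher in HCR, by 0.34 ± 0.08, 0.27 ± 0.07 and 0.38 ± 0.10 (adjusted p = 0.0156, 0.0211 and 0.0236; Tap2 by 0.185 without background correction). The immunoproteasome gene Psmb8, named after its value was seen, was the fourth higher in HCR, at 0.41 ± 0.11. RT1-A1 and RT1-A2 were the 2 members higher in LCR, and 9 members were higher in HCR and 3 in LCR when adjusted over the list alone. Ifit1, higher in LCR, and Oas1k and RT1-CE15, higher in HCR, are not in the list. On chromosome 20 RT1-A2 and RT1-A1 are next to each other among the tested genes, with a correlation of 0.77 within the lines. Tap2 and Psmb8 are next to each other there as well (0.28). Whether an inherited segment lies behind these calls was not tested. The list passed within rats 1 to 12 (adjusted p = 0.0437), within rats 13 to 24 (0.0040) and with the batch as a block (0.0026).

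Immediate early genes, which are induced within minutes by stimuli such as contraction or stress, were higher in LCR muscle. Their difference was negative for 16 of 17, with a median of -0.39 (camera adjusted p = 9.94e-06; adjusted p = 0.296 with an estimated correlation). Over all genes 3 passed: Egr1, given above, Ier2 at -0.64 ± 0.15 (adjusted p = 0.0172) and the nuclear receptor gene Nr4a2 at -0.92 ± 0.26 (adjusted p = 0.0431), and 6 passed when adjusted over the list alone. The Nr4a2 call ended in 17 of the 24 fits that left out 1 array, with 0.0774 without LCR replicate 10. The Nr4a2 difference was -0.51 without background correction. The list level was 0.24 ± 0.49 in LCR and -0.24 ± 0.24 in HCR (SD, n = 12 each). The mean difference was -0.19 in rats 1 to 12 and -0.77 in rats 13 to 24, with camera adjusted p of 0.248 and 3.73e-11 and of 1.13e-05 with the batch as a block. Exact permutation tests of the list level, two-sided with 6 rats per line, gave p = 0.364 in rats 1 to 12 and p = 0.0043 in rats 13 to 24.

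**Figure D2:**
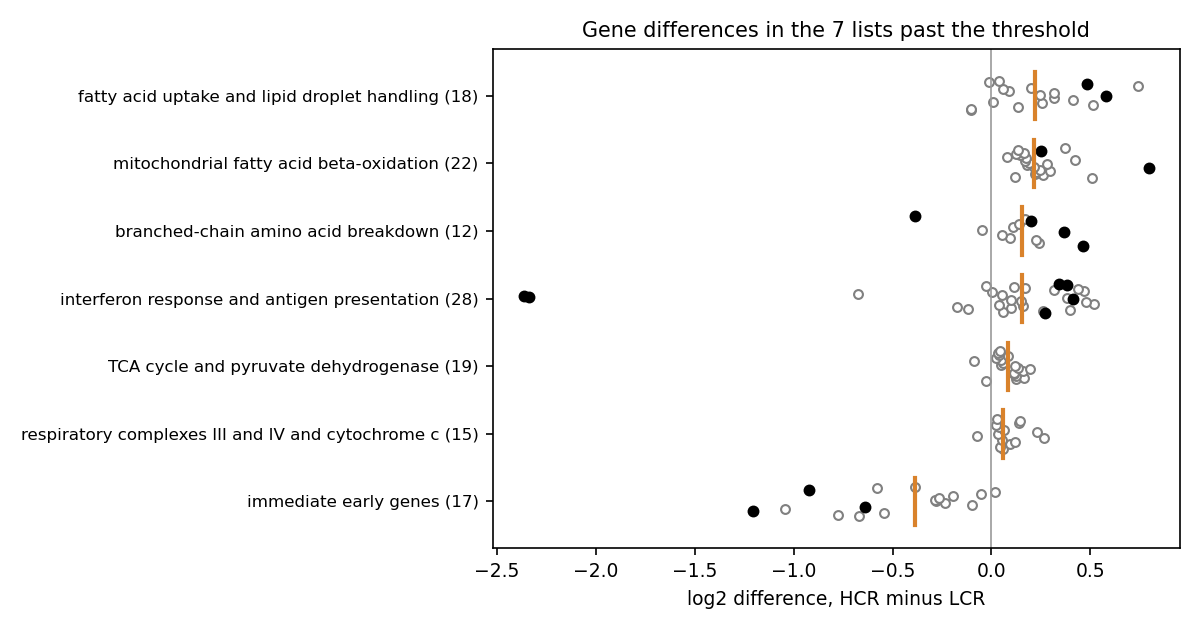
Log2 difference, HCR minus LCR (horizontal axis), of each tested gene in the 7 lists that passed, with the number of genes in brackets. Filled points passed an adjusted p of 0.05 over all genes, open points did not, and orange bars mark the list medians. All 22 beta-oxidation genes lie above 0 and 16 of 17 immediate early genes below 0.

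Of the regulators and fibre genes that were to be named whatever their result, those that follow did not pass, apart from the list member Prkab2. Ppargc1a, the coactivator of mitochondrial biogenesis, differed by 0.09 ± 0.12 (95% interval -0.15 to 0.33, adjusted p = 0.774) and Ppard by -0.14 ± 0.07 (adjusted p = 0.331). Prkab2, a regulatory subunit of AMP-activated kinase, was higher in LCR by a log2 difference of -0.76 ± 0.18 (adjusted p = 0.0158; -0.44 without background correction). Pdk4, an inhibitory kinase of pyruvate dehydrogenase, differed by 0.89 ± 0.31 (adjusted p = 0.107, and 0.0359 with the slow fibre level as a covariate and 0.0423 with array weights), the glucose transporter gene Slc2a4 by 0.15 ± 0.06 (0.191), the growth factor gene Vegfa by 0.19 ± 0.15 (0.583) and the myostatin gene Mstn by -0.43 ± 0.27 (0.475). Without LCR replicate 5 Vegfa differed by 0.082 and Mstn by -0.25, and with the Myh2 to Myh4 ratio as a covariate by 0.046 and 0.15. Between rats 1 to 12 and 13 to 24 the difference of Ppargc1a went from -0.03 to 0.21, that of Cs from -0.23 to 0.17 and that of Slc2a4 from 0.05 to 0.25. Myh2 differed by 0.69 ± 0.24 (adjusted p = 0.103, and 0.0448 without HCR replicate 8) and Myh4 by -0.41 ± 0.29 (0.528). The slow myosin gene Myh7 differed by 0.70 ± 0.83 (adjusted p = 0.741), with 15.02 ± 0.73 in HCR and 14.32 ± 2.99 in LCR (SD, n = 12 each). Its sign turned without LCR replicate 5 (-0.16) and with the Myh2 to Myh4 ratio as a covariate (-0.57). Myh4 differed by -0.25 without LCR replicate 5. Ppara was too dim to be tested, and Myh1 and Pecam1 had no named probe.

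Arrays differed in fibre and cell type markers within the lines. The level of 13 slow fibre genes was -4.99 on LCR replicate 5 and -2.16 on HCR replicate 11, against -0.61 or more on the others, and Myh7 was at 4.84 on LCR replicate 5. Without these 2 arrays, an alternative chosen after the data were seen, 356 genes passed, 164 higher in HCR and 192 higher in LCR, 251 of them among the 284. The beta-oxidation list then had a median of 0.17 (camera adjusted p = 5.84e-07), the lipid list 0.22 (0.0014), the tricarboxylic acid cycle 0.07 (0.0565), complexes III and IV 0.05 (0.0346), branched-chain amino acid breakdown 0.12 (0.0165), the interferon list 0.17 (0.0014) and the immediate early list -0.51 (3.85e-07). Adipocyte markers did not pass with all arrays (adjusted p = 0.510) and did without these 2 (0.0382). Aqp7, a marker of adipocytes, was the 1 member of that list to pass over all genes, and the list level was 1.62 on HCR replicate 2 and 1.31 on LCR replicate 5. Blood and erythroid genes did not pass (0.651), with Hbb-b1 the 1 of 7 members past the threshold.

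**Figure D3:**
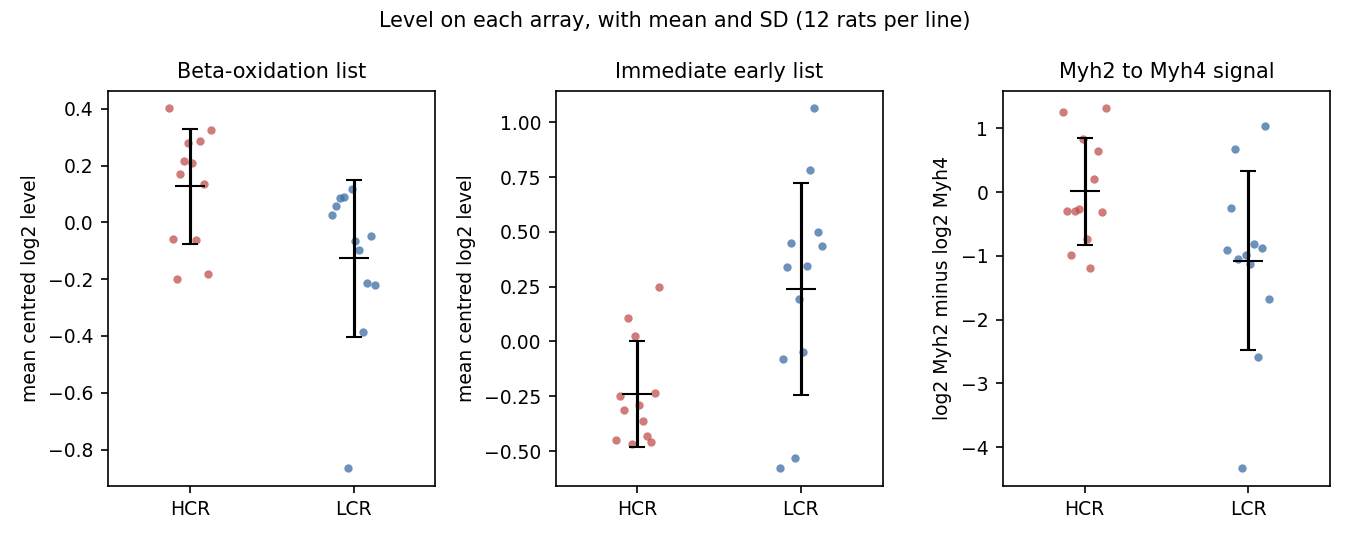
Left and middle, mean centred log2 level of the beta-oxidation and the immediate early lists on each array; right, log2 Myh2 minus log2 Myh4. Points are rats, and black marks and bars give the mean and SD of 12 rats per line. The beta-oxidation level reaches down to -0.86 in LCR, the immediate early level up to 1.06 in LCR, and the ratio averages 0.02 in HCR and -1.08 in LCR.

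The remaining lists did not pass the camera test. Adjusted p were 0.0544 for respiratory complex I, with 21 of 27 differences positive, 0.0734 for peroxisome genes and 0.0949 for ATP synthase. These 3 results turned on single arrays and on the processing. With 1 array left out complex I passed in 11 of 24 fits (0.0057 without HCR replicate 11 to 0.463 without LCR replicate 5), peroxisome genes in 5 and ATP synthase in 2. With median scaling all 3 passed as higher in HCR (9.12e-05, 0.0300 and 2.13e-04). Over 23 settings other than leaving out 1 array, complex I passed in 9, peroxisome genes in 4 and ATP synthase in 2, each time as higher in HCR. For complex I these included no background correction (0.0355), cyclic loess (0.0259) and the authors' processed values (0.0354). By the directional fry test peroxisome genes passed as well (0.0310). The peroxisomal transporter gene Abcd3 was higher in HCR by 0.32 ± 0.08 (adjusted p = 0.0345), a call that ended in 9 of the 24 fits that left out 1 array, with 0.0621 without HCR replicate 1. Mitochondrial biogenesis regulators had 0.163 (0.0309 by the directional fry test, higher in LCR), and mitochondrial ribosome and import genes 0.417, with a median of 0.05 and a mean of -0.01; beside Mrps10, the import gene Timm22 was higher in LCR (-0.29 ± 0.08, adjusted p = 0.0300, and 0.0531 without HCR replicate 1). Endothelial markers had 0.163, with the transcription factor gene Sox18 higher in HCR by 0.46 ± 0.13 (adjusted p = 0.0439), and by 0.24 without background correction. The Sox18 call ended in 15 of the 24 fits that left out 1 array, with 0.0759 without LCR replicate 9. Atrophy genes had 0.883, with the ubiquitin ligase gene Trim54 higher in LCR (-0.34 ± 0.10, adjusted p = 0.0484, and 0.0817 without LCR replicate 10). The Trim54 call ended in 14 of the 24 fits that left out 1 array and in 12 of the other settings. Antioxidant genes had 0.931, with the thioredoxin reductase gene Txnrd1 higher in LCR (-0.55 ± 0.14, adjusted p = 0.0264). Median scaling ended the calls of Timm22, Trim54, Txnrd1 and Nr4a2 (adjusted p = 0.268, 0.282, 0.0528 and 0.0529). Cytosolic ribosomal proteins had 0.554, with a median of -0.03 and a mean of 0.01. Among them Rpl30, at 2.32 ± 0.84 with an SD of 3.11 in LCR, did not pass (adjusted p = 0.124). Rpl17 was higher in HCR by 0.41 ± 0.05 on all 12 arrays against the LCR median (adjusted p = 1.61e-05). Glycolysis genes had 0.201, insulin signalling 0.535, slow fibre genes 0.803, fast fibre genes 0.883, hypoxia genes 0.703, fibroblast and matrix genes 0.803, leukocyte markers 0.931, Schwann cell markers 0.535, neuromuscular junction genes 0.436, heat shock genes 0.826 and clock genes 0.482. The pericyte list had 4 tested genes and was not tested. In simulated log2 values with 12 arrays per line, drawn independently per probe, the same probe test recovered 44% of probes shifted by 0.25, 88% at 0.5, 98% at 1 and 100% at 2, with 50 probes per size among 10384.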

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

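The alternatives with fibre covariates or without 2 arrays were chosen after the data were seen. Unless a cause is given, the cause was not tested. With an estimated correlation 0 lists passed, which widens the error of lists whose genes vary together. Median scaling gave 243 genes higher in HCR. Without a filter, where more probes share the adjustment, 209 probes passed, with 83 genes higher in HCR and 74 higher in LCR. It ended 12 of the 39 calls of named genes: Hbb-b1, Aqp7, RT1-A1, Egr1, Pnpla2, Timm22, Abcd3, Mccc1, Sox18, Trim54, Txnrd1 and Nr4a2. Array weights gave 603 probes and 220 genes higher in LCR. With 12 of the 24 rats the counts of probes and genes were lower. Rats 1 to 12 gave 36 probes, 15 and 12 genes and 3 lists, and rats 13 to 24 gave 78 probes, 19 and 37 genes and 7 lists. Fewer rats and a difference between these batches cannot be told apart here. The slow fibre covariate gave 217 genes higher in LCR, and without the 2 arrays 620 probes and 237 genes higher in LCR. With the Myh2 to Myh4 covariate 3 lists passed: 2 of the 7, the interferon and the immediate early lists, and slow fibre genes, not called otherwise and then higher in LCR (adjusted p = 6.40e-04, and 0.0017 without the 2 arrays). The other 5 calls ended, and the median of the tricarboxylic acid cycle list changed sign, from 0.085 to -0.016. Without the 2 arrays this covariate gave 95 genes higher in HCR and 7 lists, adipocyte markers among them (0.0149, higher in HCR), and of the 7 main calls those of the tricarboxylic acid cycle and of complexes III and IV ended (0.497 and 0.478). At an adjusted p of 0.01, 45 genes were higher in HCR and 34 in LCR. Leaving out 1 array gave 250 to 550 probes, 94 to 189 genes higher in HCR, 91 to 206 higher in LCR, and 5 to 10 lists, lowest without HCR replicate 1 for the genes and without LCR replicate 5 for the lists. Of 39 named genes past the threshold, 29 kept their call in each fit with 1 array left out. Over the other settings, 619 of their results kept the call, 110 lost it and none reversed. The Myh2 to Myh4 covariate ended 10 of the 39 calls, and 12 without the 2 arrays. Without background correction all 39 passed, each with a smaller difference, 17 of them by over 1.5 times, since the signal of dim probes lies near background; among them RT1-A2, Plekhf2, Rfc2 and Ifit1 were undetected on part of the HCR arrays.

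With a replicate block, 445 probes passed, with 134 genes higher in HCR, 174 higher in LCR and 8 lists; 229 of these genes were among the 284. The numbers do not pair the rats by the check made: arrays of the same number had deviations correlated by over 0.1 in 4 of 12 pairs (-0.14 to 0.38), and 4 of 24 arrays correlated best with their own number.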

Other observations

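Tests chosen after the result was seen are those of the 2 arrays poor in slow fibre genes, of the slow fibre level, of rats 1 to 12 against 13 to 24, of second probes, of the other splits and of gaps within a line, the last in place of an absolute gap of over 1 log2, whose result (4 of the 15 genes over 1 log2 and 0 of the other 269) had been seen. Those of the Myh2 to Myh4 ratio and of neighbouring genes were stated before their result was seen, and how each is read was made more cautious afterwards: the ratio now has to give the same answer without the 2 arrays, and a number of neighbours within the random range no longer counts against chromosome segments.

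Outside the fixed lists, the genes of this paragraph passed the threshold and were chosen after their values were seen. Higher in HCR were Acad11, an acyl-CoA dehydrogenase, at 0.76 ± 0.13 (adjusted p = 0.0019), Eci3, an enoyl-CoA isomerase, at 0.59 ± 0.12 (0.0085), Acot3, an acyl-CoA thioesterase, at 0.48 ± 0.09 (0.0045), Tspo, a protein of the outer mitochondrial membrane, at 0.61 ± 0.11 (0.0034), Coq7, of ubiquinone synthesis, at 0.57 ± 0.15 (0.0364), and Opa1, which fuses inner mitochondrial membranes, at 0.47 ± 0.11 (0.0136). The muscle cytokine gene Il15 was 0.58 ± 0.11 higher (0.0035), Apoe 0.47 ± 0.12 (0.0228), and Odc1, the ornithine decarboxylase of polyamine synthesis, 0.59 ± 0.12 (0.0085). Higher in LCR were the cholesterol transporter gene Abca1 at -0.54 ± 0.09 (0.0019), Pitx1, a transcription factor of the hindlimb, at -0.62 ± 0.15 (0.0161), the collagen chaperone gene Serpinh1 at -0.56 ± 0.16 (0.0403), and the proteasome assembly gene Pomp at -0.56 ± 0.09 (6.70e-04). Other mitochondrial genes outside the lists passed as higher in LCR, such as Mrpl45 at -0.48 and Isca1 at -0.40. The genes picked here therefore do not show a common direction of mitochondrial genes. All are limma estimates with 12 rats per line, no enrichment was tested for them, and their calls with 1 array left out are not given.

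Of the splits drawn, 1 of 100 splits of the 24 arrays, the real one, gave as many as 401 probes between the groups, and the highest other gave 27. Random assignment of independent rats to groups is therefore an unlikely source of that number. The splits treat the rats as independent, and as litters are not given, they cannot exclude an effect of relatedness within a line.

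Beta-oxidation genes were higher in HCR with a median difference of 0.216 (quartiles 0.17 and 0.28). The median was 0.170 without the 2 arrays poor in slow fibre genes (camera adjusted p = 5.84e-07), so that these 2 arrays together do not account for it. They lie in opposite lines, so that leaving out both says little about reliance on 1 of them. Without LCR replicate 5 alone the camera adjusted p was 7.13e-05. With the slow fibre level as a covariate the median was 0.188 (camera adjusted p = 8.38e-09). Over the alternatives the adjusted p of the list ranged from 3.56e-10 to 0.422, the highest with an estimated correlation. The slow fibre level averaged 0.077 ± 0.770 in HCR and -0.077 ± 1.598 in LCR (SD, n = 12 each). With the lines so close in it, the covariate could change the median little and cannot decide on slow fibre content. With the ratio of Myh2 to Myh4 as a covariate the median fell to 0.031 (quartiles -0.01 and 0.10; adjusted p = 0.333), since the differences themselves shrank, and 16 of 22 genes stayed positive. Without the 2 arrays that covariate left 0.08 against 0.17, and the list passed (0.0149), as did adipocyte markers, higher in HCR (0.0149). A hypothesis is therefore that a higher share of type IIa relative to type IIb fibres in HCR muscle, by line or by the piece sampled, may account for much of the difference, and whether it accounts for all of it cannot be told apart from a difference within fibres. The ratio differs between the lines, by 1.09 with all arrays and by 0.83 without the 2 arrays, so that a covariate also removes what goes along with the line.

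Immediate early genes were higher in LCR with a median of -0.387, and of -0.392 with the slow fibre level as a covariate (camera adjusted p = 4.09e-06, in a range of 3.73e-11 to 0.296 over the alternatives). That level differs little between the lines, so that slow fibre content is an unlikely source and the covariate could change the median little. A shift shared by all rats of a batch cannot give this difference, since each batch holds 6 rats per line, and the list passed with the batch as a block (camera adjusted p = 1.13e-05). Whether the difference is confined to part of the rats stays open: the mean difference was -0.19 in rats 1 to 12 and -0.77 in rats 13 to 24, and permuting these batches within the lines 100000 times gave p = 0.0636 for the difference between them. With 6 rats per line in each, a difference confined to part of the rats cannot be told apart from one present in all rats. Handling before sampling, which could raise these genes within minutes, and a difference between the lines are not recorded apart from the line and were not tested.

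Separate levels inside a line, with a gap of over 1 log2, were seen in 4 of the 15 genes over 1 log2 and not in the other 11, in 0 of the other 269 genes past the threshold, and in 43 of the 7033 genes that did not pass. For RT1-A2 and Plekhf2 the lower set held 9 and 7 HCR arrays, and their probes were detected on 3 and 5 of the 12 HCR arrays. The lower level of these 2 genes therefore lies near background, where the size of a difference depends on the background step. As a share of the line's range, the largest gap averaged 38.8% in the 15 genes and 26.2% in the 269 (two-sided permutation p = 1.00e-05, over 100000 permutations), but this was run on the genes whose levels had prompted it and supports no explanation. Inherited alleles that both occur within a line therefore stay a hypothesis, which cannot be told apart from other sources without genotypes. A sequence variant under the probe cannot be told apart either. In 4 of 5 genes with a second tested probe that probe had the same direction, and in 1 it also passed, but 0 of these 5 differ by over 1 log2.

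The number of neighbouring genes past the threshold gives no evidence of chromosome segments that differ. Of the 284 genes, 64 had another within 3 tested genes on the same chromosome, gene families left out, against a median of 58 (95% range 41 to 76) in 10000 random sets. With about 58 such genes by chance, a few chromosome segments that differ between the lines could be missed, so that the number excludes none and the bound stated in advance was too strict. Among the tested genes of chromosome 6, Dnal1, higher in LCR, lies between Acot3 and Ptgr2, both higher in HCR. Within the lines Acot3 and Ptgr2 had a correlation of 0.63, and Dnal1 had -0.52 and -0.55 with them. RT1-A2 and RT1-A1, a family pair on chromosome 20, had 0.77. Some other pairs varied little together, such as Spn and Cd2bp2 on chromosome 1 (-0.09). These pairs were picked after their values were seen and were not tested.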
